A study of Mus musculus with 24 samples.

How the data were processed

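Polyadenylated RNA of the tibialis anterior was measured by sequencing in 24 libraries, 6 for each of 4 groups of male mice: young (4 months) and aged (24 months) animals, given daily saline or dexamethasone (1 mg/kg/day) for 7 days and sampled 6.5 h after the last injection. Per the labels' protocols, separate mice were randomised within each age, libraries were built from 300 ng of total RNA with a poly(A)-selecting kit, and paired reads of 150 bases were generated on a NovaSeq X Plus.

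The deposited table holds values on a log2 scale that the authors call rlog, the regularised logarithm of the DESeq2 software, and DESeq2 1.30.1 and the mm10 assembly are named per the submitters' processing notes. The rlog transform divides counts by a size factor per library and shrinks the differences of genes with few counts toward 0, so a fold change taken from it understates the change of weakly expressed genes. The aligner, the counting tool, the annotation and whether strand was used are not given in the sources used here. The table has 24982 genes with no duplicated symbol, and its columns of values all belong to the 24 libraries. It holds no counts, so library depth was unknown, and the precision of each value was judged only from the spread between mice. Of the genes, 619 were exactly 0 in all 12 aged libraries and not in the young, 858 exactly 0 in all 12 young libraries and not in the aged, and none was 0 in only some libraries of an age or in 1 treatment group only. The ages had therefore been transformed apart with both treatments together, and the comparisons of aged with young levels that the design called for were not run. No mitochondrially encoded gene symbol was in the table used here. Symbols were matched to the RefSeq gene table of GRCm38.p6 for 24417 genes, and coordinates, counted from 1, were taken from it, GRCm38 being the same assembly as mm10. Exon overlaps between genes were taken from GENCODE vM21.

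Within each age, dexamethasone was compared with vehicle by limma 3.58.1 in R 4.3.3, as a linear model of the deposited values with empirical Bayes moderation and an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Genes with a mean value of at least 3 over the 12 libraries of the age were tested and constant genes left out. Errors are given as the SD over 6 libraries or the standard error of the difference. The design had laid down a fit in which all 4 groups share 1 estimate of the spread, for both ages. It was replaced by a fit of each age alone. In simulated data built on the real values, with 200 changed genes per draw among 12879 and 3 draws, the share of false calls was 18.6% in the aged and 5.60% in the young with the shared fit, and 4.60% and 2.88% with each age alone. Of genes changed by 0.5 on the log2 scale the separate fits recovered 91.0% (aged) and 93.0% (young), and the shared fit 95.3% and 92.0%. Of those changed by 1 the separate fits recovered 95.3% and 98.0%, and the shared fit 99.0% and 97.7%. In these simulated data the shared fit thus found more of the changed genes in the aged, with more false calls. The simulation took each gene's sample SD at each age as its true SD, which can overstate the false calls of the shared fit. It drew noise independently for each gene, so variation shared between genes was left out. Its shares are therefore not error rates of the fits to the real data. The values of the 2 ages were also not on a common scale. Both fits had been run on the real data before this choice was made, and the counts of the shared fit are printed beside the others. The test of whether the effect of dexamethasone differed between ages used the shared fit. The design had asked for that test only if the ages had been normalised together, so it is an added comparison.

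A total of 41 gene lists, 31 of pathways and 10 of cell type markers, were tested by camera on ranked moderated statistics with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 genes tested. One list had no member in the table. Some genes were on several lists, so the results of those lists were not independent of each other. Alternatives were camera with a correlation estimated for each list, which is more conservative, and fry, which tests whether a list's genes move one way and does not compare them with other genes. An exact permutation test of each list's mean value per library, two-sided over all assignments of the 12 libraries of an age, was added after the data had been seen, and the smallest p it can give is 0.00216. Members past the threshold were counted over all genes tested and adjusted over the list alone.

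The gene lists, the list of alternatives, the first design and the rule for naming genes were set before the data were examined. The rule allows the 10 largest rises and 10 largest falls of a comparison among genes past the threshold with a mean of at least 5 and all dexamethasone libraries on 1 side of the vehicle mean, leaving out unnamed and predicted genes, up to 4 members with the smallest p from each list, and a fixed set of glucocorticoid, atrophy and growth genes whatever their p. From the genes it allows, 86 were taken after their values had been seen and before the alternative fits were run, and any other gene is marked in the text. One of them is not reported here.

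Alternatives were other filters on low values, centring each library on its median, quantile normalisation, moderation without the trend, robust moderation, library weights, stricter thresholds, an exact permutation test gene by gene, the replicate number as a block, and leaving out each library in turn. The shared spread of the first design was kept as an alternative once the fit of each age alone, chosen after the data had been seen, had replaced it. Added after the data had been seen were a minimum mean of 8 for the difference of effects, and fits without the 3 libraries that stand apart (aged vehicle 1, young vehicle 3 and young dexamethasone 5). These carried the largest weights of their age in the main pattern of variation within groups (absolute loadings 0.586, 0.547 and 0.512). Chance was assessed on 100 random splits of the libraries of an age, or 100 regroupings across ages within a treatment, the real one included, out of 462 possible splits per age. Extreme libraries were sought with Dixon's test in each group of 6. Simulation and testing used R, and gene tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.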

Results

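Messenger RNA of the tibialis anterior, a mainly fast-twitch muscle at the front of the lower leg, was sequenced in male C57BL/6 mice, an inbred laboratory strain, at 2 ages. Young mice were 4 months old and aged mice 24 months old. Within each age, mice had been randomised to saline (vehicle) or to dexamethasone, a synthetic glucocorticoid that activates the glucocorticoid receptor, at 1 mg/kg/day by subcutaneous injection for 7 days, and the muscle was collected 6.5 h after the final dose. Each of the 4 groups held 6 libraries, 24 in all. The deposited table gave 24982 genes as rlog values on a log2 scale, between −2.21 and 19.27. It gave no counts, so the depth of each library was unknown and no counting interval could be attached to a value. The 2 ages had been transformed apart, which was visible from 619 genes listed at exactly 0 in all 12 aged libraries and not in the young, and 858 genes in the reverse position. Levels were therefore compared within an age. No pair of libraries was identical, and the closest pair, young dexamethasone 3 and 4, had a median absolute difference of 0.0593 across genes.

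The first question was what 7 days of dexamethasone changed in aged muscle. Of 12932 genes tested, 533 were higher and 289 lower with dexamethasone. The steepest rise was that of Lcn2, which encodes lipocalin 2, a secreted protein that binds iron-carrying siderophores: it went from 8.64 ± 0.91 (SD, n = 6) with vehicle to 10.82 ± 0.35 with dexamethasone, a difference of 2.18 ± 0.34 (SE) on the log2 scale or 4.52-fold (limma adjusted p = 0.00163). Greb1, an oestrogen-responsive gene, rose by almost as much with far less scatter, from 5.88 ± 0.11 to 8.05 ± 0.13 (2.17 ± 0.07, adjusted p = 7.53e-10), and their order turned with single libraries left out, Lcn2 being at 2.00 without aged vehicle 3. The steepest fall was that of Rrad, a small GTPase that restrains voltage-gated calcium channels, from 9.12 ± 0.94 to 7.35 ± 0.46 (−1.78 ± 0.37, adjusted p = 0.0105). All 6 dexamethasone libraries lay on the same side of the vehicle mean for each of these genes.

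The 10 largest rises in the aged also included Odf3l2 (1.91), the receptor tyrosine phosphatase gene Ptprf (1.90), Pag1, a membrane adaptor that recruits the Src-inhibiting kinase Csk (1.86), the transcription factor gene Sox4 (1.62), Pnmt, which makes adrenaline from noradrenaline (1.56), Rnf169, a DNA damage response protein (1.55), and the collagen V chain Col5a1 (1.36 ± 0.11, adjusted p = 6.03e-06). After Rrad, the largest falls were in Ppp1r27, a regulatory subunit of protein phosphatase 1 (−1.43), the interferon-inducible GTPase gene Gbp4 (−1.06), Chac1, which degrades glutathione (−0.98), and Cyp26b1, which clears retinoic acid (−0.97). They were followed by Gbp9 (−0.90), Runx1, a transcription factor induced in denervated muscle (−0.87), Nmrk2, a nicotinamide riboside kinase (−0.83), Ky, a muscle protein needed for fibre integrity (−0.77), and Podxl, a sialomucin of endothelium (−0.76). Among the 822 genes past the threshold the median absolute difference was 0.38, with 253 at 0.5 or more and 33 at 1 or more. The Cyp26b1 call was the least firm of these, holding in 5 of 12 fits that each left out 1 library, with an adjusted p of up to 0.0782. Runx1 held in 10 of 12, the exceptions being the fits without aged vehicle 5 and without aged dexamethasone 4 (adjusted p up to 0.0580).

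Glucocorticoid receptor targets formed the group with the most members past the threshold. Of 30 measured, 13 were higher and 1 was lower, and 19 were higher and 3 lower when adjusted over the list alone. Fkbp5, a co-chaperone that dampens receptor signalling, rose from 12.18 ± 0.35 to 13.11 ± 0.05 (SD, n = 6), a difference of 0.93 (adjusted p = 6.23e-04). Klf15, a transcription factor that directs amino acid catabolism, rose by 0.62, and Nfkbia, the inhibitor of NF-kB, by 0.65. The 1 lower member was Bcl6, a transcriptional repressor named here after its values were seen (−0.42, adjusted p = 0.0248). The list mean was higher in 6 of 6 dexamethasone libraries, by 0.40 (exact permutation test over all splits of the 12 libraries, p = 0.00216, the smallest it can give, adjusted p = 0.0433). Camera with its preset correlation called the list at an adjusted p of 9.69e-10, and with an estimated correlation the adjusted p = 0.603. Tsc22d3 and Per1, both known receptor targets, did not pass, at −0.02 and −0.01 (adjusted p = 0.937 and 0.982).

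Negative regulators of mTORC1, the kinase complex that promotes protein synthesis, had 3 of 24 members higher and none lower (5 higher and 1 lower adjusted over the list alone). Sesn1, a leucine-sensing sestrin, rose from 10.43 ± 0.24 to 11.32 ± 0.17 (SD, n = 6; 0.89, adjusted p = 1.93e-04), Ddit4, also called REDD1, rose by 0.87 (adjusted p = 0.00706), and Klf15 was the third. All 3 are also on the glucocorticoid receptor target list, so the results of these lists are not independent. The list mean was 0.13 higher in the dexamethasone libraries and missed the threshold after adjustment (exact permutation test, adjusted p = 0.0577). Camera called it at 0.0366, against an adjusted p = 0.603 with an estimated correlation. The call ended without aged vehicle 6, aged dexamethasone 5 or aged dexamethasone 6 (adjusted p up to 0.0612) and with quantile normalisation (0.0661). In the insulin, IGF-1, Akt and mTORC1 pathway list 1 of 32 members was higher and 1 lower, with the same counts adjusted over the list alone. These were the receptor gene Igf1r (0.28, adjusted p = 0.0459) and Irs1, its adaptor (−0.39, adjusted p = 0.0265), which held in 2 and 8 of the 12 fits with 1 library left out (adjusted p up to 0.0945 and 0.0639). Igf1 itself did not pass (−0.22, adjusted p = 0.323), and neither did Mstn, encoding the growth inhibitor myostatin (0.55, adjusted p = 0.0580).

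Of 24 ubiquitin ligases and related genes of muscle atrophy, 3 were higher and 1 lower, with the same counts adjusted over the list alone. Camera did not call the list (adjusted p = 0.408). Ubr2, a ligase of the N-end rule pathway, rose by 0.37 (adjusted p = 0.00329). Trim63, or MuRF1, which targets myofibrillar proteins, rose from 14.24 ± 0.26 to 14.68 ± 0.18 (SD, n = 6; 0.44, adjusted p = 0.0395), a call kept in 3 of 12 fits with 1 library left out (adjusted p up to 0.0965). The others past the threshold were Zfand5, which activates the proteasome (0.26), and Fbxo40, a ligase that targets the insulin receptor substrate (−0.30), each kept in 9 of 12 such fits (adjusted p up to 0.0591 and 0.0535). Fbxo32, or atrogin-1, the other classic atrophy ligase, did not pass: it was 13.21 ± 0.39 with vehicle and 13.14 ± 0.33 with dexamethasone (−0.07, adjusted p = 0.908). In the autophagy and lysosome list 5 of 34 members were higher and 1 lower (5 and 2 adjusted over the list alone, camera adjusted p = 0.732), among them the mitophagy receptor gene Bnip3 (0.22, not past the threshold with quantile normalisation, adjusted p = 0.0816) and the FoxO-induced autophagy regulator Depp1 (0.52).

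Of 31 genes of fatty acid uptake and oxidation, 3 were higher and none lower (5 and 0 adjusted over the list alone): Ppara, a nuclear receptor that drives fatty acid oxidation (1.22, adjusted p = 6.23e-05), Eci2, an enoyl-CoA isomerase (0.45), and Ppard (0.42). Of 30 genes of amino acid and branched-chain catabolism, 3 were higher and none lower (8 and 0 adjusted over the list alone), among them glutamine synthetase, Glul (0.50, adjusted p = 0.00173), and Dbt, a subunit of the branched-chain ketoacid dehydrogenase (0.29, adjusted p = 0.0122). The third, the aminotransferase gene Bcat2 (0.19, adjusted p = 0.0485), held in 1 of 12 fits with 1 library left out (adjusted p up to 0.114). Camera called both lists (adjusted p = 1.62e-04 and 0.00405), with adjusted p = 0.800 for each with an estimated correlation, and the exact permutation test of the list means did not (adjusted p = 0.0989 and 0.0866). The amino acid call ended with quantile normalisation (adjusted p = 0.111).

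Among interferon response and antigen presentation genes, 5 of 29 measured were lower and none higher, and 19 were lower and none higher when adjusted over the list alone. The 5 were Psmb8, an immunoproteasome subunit (6.59 ± 0.22 to 5.99 ± 0.12, SD, n = 6; −0.60, adjusted p = 0.00173), the peptide transporter gene Tap1 (−0.60), Ifit3 (−0.57), the interferon signal transducer gene Stat2 (−0.43), and Gbp2 (−0.70, named after its values were seen). The Ifit3 call held in 5 of 12 fits with 1 library left out (adjusted p up to 0.0700). The list mean was 0.33 lower, in 6 of 6 dexamethasone libraries, and missed the threshold after adjustment (exact permutation test, adjusted p = 0.0649). Camera called it at 5.29e-10, against an adjusted p = 0.739 with an estimated correlation. Markers of macrophages and of fibro-adipogenic progenitors, the matrix-producing stromal cells of muscle, moved the same way in these libraries, with list means 0.26 lower in each case. Each of these marker lists had 1 of 14 members lower, the chemokine receptor gene Ccr2 (−0.49) and Hic1 (−0.48), respectively, and none higher (1 and 2 lower adjusted over the list alone). Camera called them at 0.0427 and 0.0128, against adjusted p = 0.865 for both with an estimated correlation, and the exact permutation test did not (adjusted p = 0.341 and 0.357). The macrophage call was kept in 6 of 12 fits with 1 library left out. It ended without aged vehicle 2, 3 or 6 or aged dexamethasone 3, 4 or 6 (adjusted p up to 0.134). The progenitor call was kept in 10, the exceptions being without aged vehicle 2 or aged dexamethasone 6 (up to 0.0773). The Hic1 call held in 4 of 12 fits with 1 library left out (adjusted p up to 0.0833).

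With all 4 groups sharing 1 estimate of the spread, the fit first laid down for this comparison, 710 genes were higher and 534 lower in the aged, and Rrad no longer passed (adjusted p = 0.0685). With the aged fitted alone, the number of lower genes was 289 with all libraries, 167 without aged dexamethasone 4 and 181 without aged dexamethasone 5. Camera called at least 7 lists, the number in the real comparison, in 93 of 100 splits of the aged libraries, the real split included. Which lists the other splits called was not compared.

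**Figure D1:**
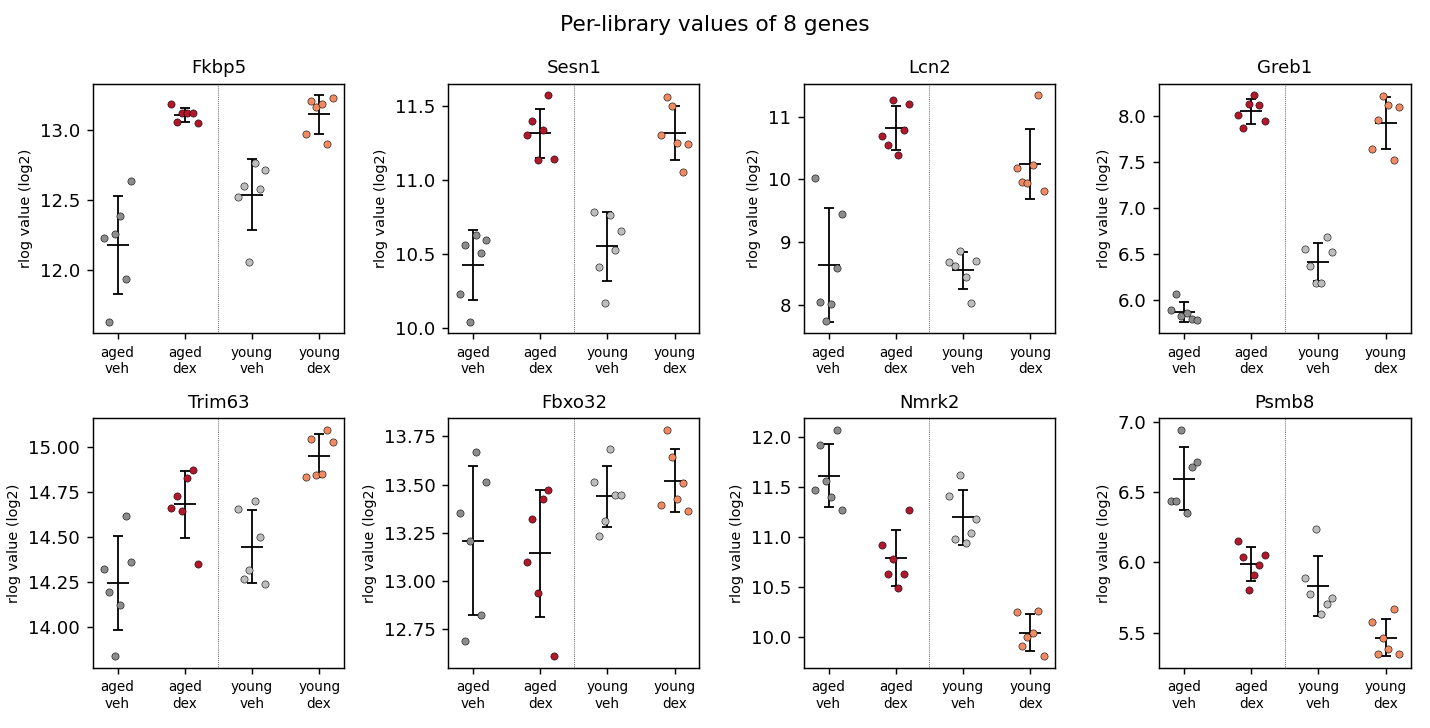
The rlog value (log2 scale) of 8 genes in each of the 24 libraries, with vehicle (veh) and dexamethasone (dex) groups of aged and young mice along the horizontal axis; each point is a library, the long dash the mean and the bars the SD of 6 libraries. Fkbp5, Sesn1, Lcn2 and Greb1 lay above the vehicle mean in all dexamethasone libraries of both ages, Nmrk2 and Psmb8 lay below it, and Fbxo32 overlapped, while levels are not comparable across the dotted line because the 2 ages were transformed apart.

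The same comparison in young muscle asked what the treatment changed at 4 months of age. Of 12866 genes tested, 478 were higher and 227 lower with dexamethasone. Lcn2 had the largest rise over all libraries, from 8.55 ± 0.29 to 10.25 ± 0.56 (SD, n = 6), a difference of 1.69 ± 0.23 (SE) or 3.23-fold (adjusted p = 6.53e-04). Ptprf rose from 7.56 ± 0.18 to 9.20 ± 0.33 (1.65 ± 0.13, adjusted p = 2.72e-05) and Greb1 from 6.42 ± 0.20 to 7.92 ± 0.28 (2.83-fold, adjusted p = 2.72e-05). The rank of Lcn2 rested on young dexamethasone 5, without which its rise was 1.47, against 1.73 for Ptprf and 1.58 for Greb1. Nmrk2 fell most, from 11.20 ± 0.27 to 10.05 ± 0.18 (−1.15 ± 0.12, adjusted p = 1.11e-04), followed by Slc4a4, a sodium bicarbonate cotransporter, from 8.90 ± 0.25 to 7.99 ± 0.17 (−0.91 ± 0.11, adjusted p = 3.76e-04).

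Further genes among the 10 largest rises in the young were Odf3l2 (1.46), the phospholipase C gene Plch2 (1.18), Rnf169 (1.16), G0s2, which inhibits adipose triglyceride lipase (2.14-fold), the interleukin-6 receptor gene Il6ra (1.08), the zinc finger gene Zfp423 (1.04), and Dio2, the deiodinase that activates thyroid hormone (1.03, adjusted p = 0.00251). The further falls were Ppp1r27 (−0.87), Gbp9 (−0.69), the metalloproteinase inhibitor gene Timp4 (−0.65), Nrp1, a co-receptor for VEGF (−0.62), Bhlhe41, a repressor of the circadian clock (−0.61), Gbp4 (−0.60), the collagen XV chain Col15a1 (−0.57) and the MHC class II gene H2-Aa (−0.56, adjusted p = 1.80e-04). All 6 dexamethasone libraries lay on that side of the vehicle mean for each of these genes. Among the 705 genes past the threshold the median absolute difference was 0.30, with 138 at 0.5 or more and 14 at 1 or more.

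Of 30 glucocorticoid receptor targets, 12 were higher and none lower in the young, and 18 were higher and none lower when adjusted over the list alone. Fkbp5 rose from 12.54 ± 0.25 to 13.11 ± 0.14 (SD, n = 6; 0.57, adjusted p = 0.00502), Cdkn1a, which encodes the cell cycle inhibitor p21, by 0.81 (adjusted p = 6.53e-04), Klf15 by 0.53 and Nfkbia by 0.41. The list mean was 0.36 higher, in 6 of 6 dexamethasone libraries (exact permutation test, p = 0.00216, the smallest it can give, adjusted p = 0.0211). Camera called it at 2.23e-14, and it was the 1 list that kept its call with an estimated correlation (adjusted p = 0.00974). Tsc22d3 (−0.03) and Per1 (0.19) did not pass (adjusted p = 0.928 and 0.286).

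Of the 24 negative regulators of mTORC1, 2 were higher in the young, Sesn1 (0.77, adjusted p = 8.73e-04) and Klf15, and none lower (3 and 0 adjusted over the list alone), and camera did not call the list (adjusted p = 0.201). Sesn1 and Klf15 are also on the glucocorticoid receptor target list. Ddit4 was 0.54 higher with dexamethasone without passing (adjusted p = 0.0796). In the insulin, IGF-1, Akt and mTORC1 pathway list 2 of 32 members were higher and none lower (2 and 1 adjusted over the list alone). The 2 higher were Igf1r (0.31, adjusted p = 0.0298) and the amino acid transporter gene Slc7a5 (0.49, adjusted p = 0.0385). They held in 4 and 5 of the 12 fits with 1 library left out (adjusted p up to 0.0753 and 0.0929). Trim63 rose from 14.45 ± 0.20 to 14.95 ± 0.12 (SD, n = 6; 0.50, adjusted p = 0.00372) and Fbxo40 fell by 0.42 (adjusted p = 7.72e-04). They were the only members of the 24 atrophy ligases past the threshold over all genes (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.865). Fbxo32 was 13.44 ± 0.16 with vehicle and 13.52 ± 0.16 with dexamethasone (0.08, adjusted p = 0.768).

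Fatty acid uptake and oxidation had 6 of 31 members higher and none lower in the young (8 and 0 adjusted over the list alone), among them Eci2 (0.44), Ppard (0.37) and the acyl-CoA thioesterase genes Acot1 (0.63) and Acot2 (0.56), close paralogs between which reads can be shared. Amino acid and branched-chain catabolism had 4 of 31 members higher and none lower (8 and 0 adjusted over the list alone), including Glul (0.54, adjusted p = 4.27e-04), Dbt (0.33) and Bcat2, the mitochondrial branched-chain aminotransferase (0.28). The mean of the amino acid list was 0.12 higher in 6 of 6 libraries (exact permutation test, p = 0.00216, adjusted p = 0.0211), whereas the fatty acid list missed the threshold (exact permutation test, adjusted p = 0.328). Camera called both at 3.91e-05, with adjusted p = 0.748 for amino acids and 0.932 for fatty acids with an estimated correlation.

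In the interferon and antigen presentation list 2 of 28 members were lower in the young and none higher, with the same counts adjusted over the list alone. These were Psmb8 (−0.37, adjusted p = 0.0365) and Psmb9 (−0.16, adjusted p = 0.0333), kept in 5 and 2 of the 12 fits with 1 library left out (adjusted p up to 0.0888 and 0.0801). Immediate early genes had 3 of 20 members higher and none lower, also adjusted over the list alone: Fosb (0.86, adjusted p = 0.0240), Maff (0.85, adjusted p = 7.04e-05) and Jun (0.35). Of 14 markers of fibro-adipogenic progenitors, 2 were lower, Lum (−0.41, adjusted p = 0.0411) and Cd34 (−0.26, adjusted p = 0.0162), and 3 adjusted over the list alone. Neither passed without young vehicle 3 and young dexamethasone 5 (adjusted p = 0.0979 for Lum in young mice and 0.0590 for Cd34 in young mice). Lum held in 3 of 12 fits with 1 library left out (adjusted p up to 0.0889), and Fosb in 9 of 12 (adjusted p up to 0.0618). Camera called these 3 lists at 7.58e-05, 0.0117 and 0.0146, all with adjusted p = 0.932 with an estimated correlation, and none passed the exact permutation test of its mean (adjusted p = 0.328, 0.604 and 0.604). The immediate early call ended without young vehicle 4 or young dexamethasone 5 (adjusted p up to 0.0967). The progenitor call ended without young vehicle 3, 4 or 5 or young dexamethasone 3 or 4 (adjusted p up to 0.123). Of 14 macrophage markers, 2 were lower, Mpeg1 (−0.41) and Ccr2 (−0.32, adjusted p = 0.0518 without young dexamethasone 4), and none higher, while 1 was higher and 2 lower adjusted over the list alone. Camera did not call the list (adjusted p = 0.0877).

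With all 4 groups sharing 1 estimate of the spread, 359 genes were higher and 110 lower in the young, and H2-Aa, Maff, Mpeg1, Cd34, Ccr2, Acot2, Ky, Lum, Slc7a5 and Psmb9 no longer passed, nor did the immediate early list (adjusted p = 0.109). Camera called at least 6 lists, the number in the real comparison, in 89 of 100 splits of the young libraries, the real split included. Young vehicle 3 and young dexamethasone 5 stood apart from their groups, and without them 455 genes were higher and 220 lower, and Lum, Cd34, Slc7a5, Psmb9 and Depp1 did not pass.

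**Figure D2:**
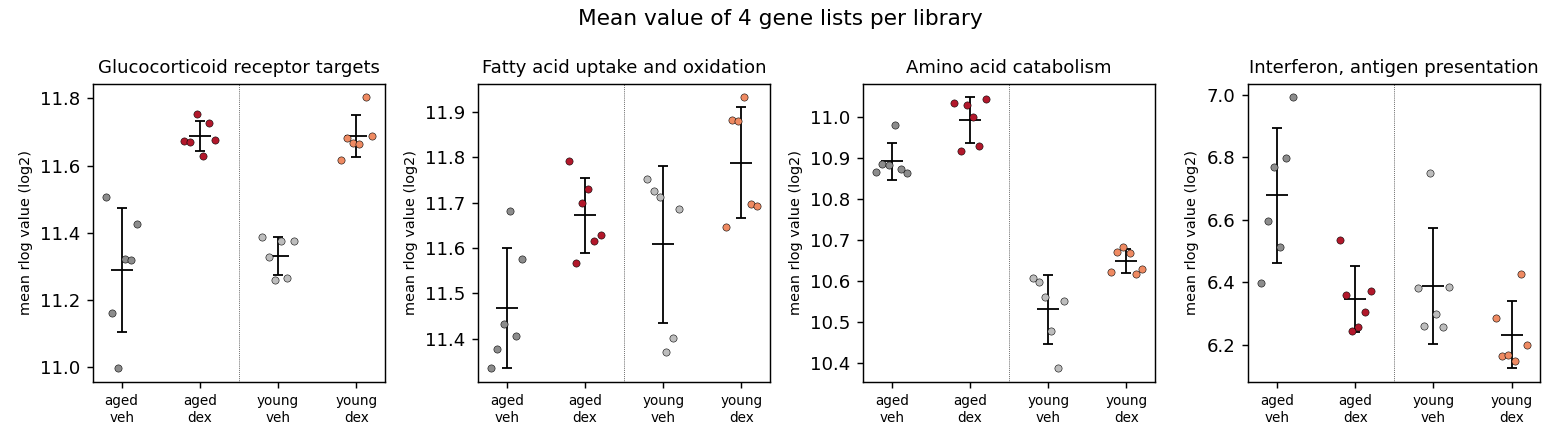
The mean rlog value (log2 scale) of the genes of 4 lists in each library, with vehicle (veh) and dexamethasone (dex) groups of aged and young mice along the horizontal axis; points are libraries, the long dash the group mean and the bars the SD of 6 libraries. Glucocorticoid receptor targets separated the treatments at both ages (0.40 higher in the aged and 0.36 in the young), the fatty acid and interferon lists overlapped between treatments, and levels are not comparable across the dotted line because the 2 ages were transformed apart.

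The series was set up to compare the response of young and aged muscle, and the responses were first laid side by side over the 12676 genes tested at both ages. Of 525 genes higher in the aged and 470 higher in the young, 283 were higher at both ages, against 19.5 for independent lists of these sizes. Of 285 and 227 lower genes, 78 were lower at both, against 5.10 for independent lists, and no gene passed in opposite directions. No library was used at both ages. The effects had the same sign in 98.8% of the aged calls and 98.0% of the young calls, and in 67.8% of the genes that passed at neither age. Across genes, which are not independent replicates, the effects correlated with Pearson's r = 0.80 and Spearman's rho = 0.632. The median ratio of the young to the aged effect was 0.647 among aged calls, and that of the aged to the young effect was 1.07 among young calls, each set having been chosen on the effect in the denominator. The SD of the deposited values within groups had a median of 0.105 in the aged and 0.0891 in the young. As the ages were transformed apart, these SDs were not on a common scale and do not show a larger spread in aged muscle.

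**Figure D3:**
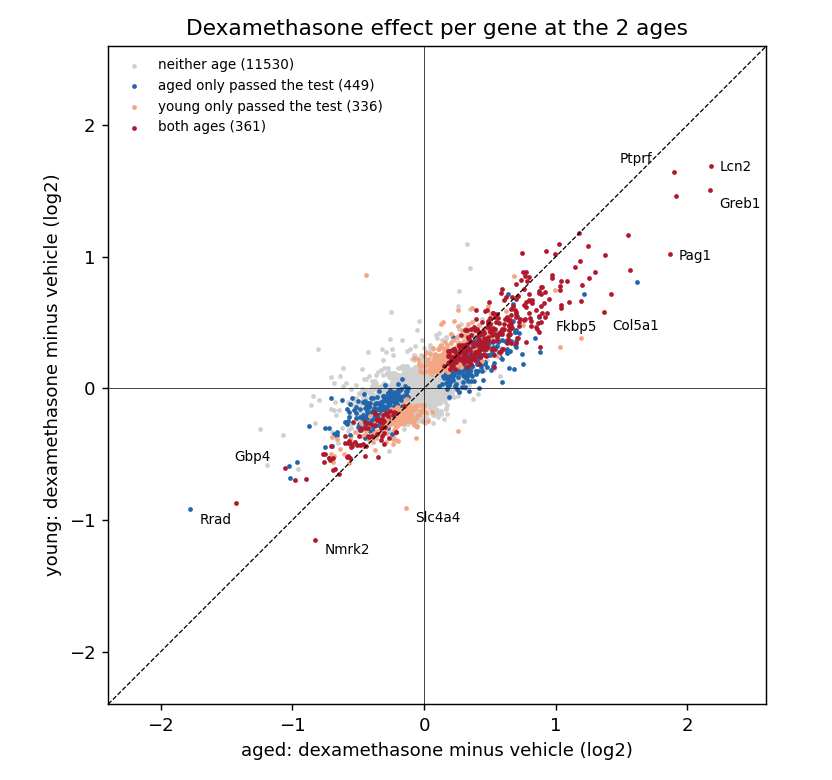
The difference between dexamethasone and vehicle (log2) of each of the 12676 genes tested at both ages, aged mice on the horizontal and young mice on the vertical axis, with genes past the threshold at 1 age, at both (361) or at neither in separate colours and a dashed line of equal effects. Genes past the threshold at both ages lie at the upper right and lower left, and none passed in opposite directions.

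Whether the effect itself differed between the ages was then tested gene by gene, as an added comparison, since the ages had been transformed apart. None of 12879 genes passed (limma with all 4 groups in 1 fit, smallest adjusted p = 0.281). At an unadjusted p under 0.05 the aged effect minus the young effect was positive for 201 genes and negative for 199. Genes allowed by the naming rule are given as values. Col5a1 rose by 1.36 in the aged and 0.58 in the young, a difference of 0.78 (adjusted p = 0.281). Tbc1d1, a Rab GTPase-activating protein that regulates glucose uptake, was 0.26 higher in the aged without passing and fell by 0.32 in the young (difference 0.58, adjusted p = 0.281). The young call held in 3 of 12 fits with 1 library left out (adjusted p up to 0.0717). Slc4a4 was −0.14 in the aged and −0.91 in the young (difference 0.77, adjusted p = 0.281). The VEGF receptor gene Kdr was 0.30 higher in the aged and −0.25 in the young, neither past the threshold (difference 0.55, adjusted p = 0.576). Fosb was −0.44 in the aged and 0.86 in the young (difference −1.31, adjusted p = 0.367). For Fkbp5 the difference of effects was 0.36 (adjusted p = 1.00). Genes past the threshold at 1 age were thus not shown to respond differently at the other.

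In the GRCm38 assembly (mm10), Lcn2 spans 32384637 to 32387739 on chromosome 2, Greb1 16670615 to 16801394 on chromosome 12, Ptprf 118208213 to 118291405 on chromosome 4, and Fkbp5 28398753 to 28486149 on chromosome 17. Sesn1 spans 41810574 to 41908436 and Nmrk2 81198170 to 81202265 on chromosome 10, Trim63 134315120 to 134329629 on chromosome 4, Rrad 104628070 to 104631350 on chromosome 8, Slc4a4 88793858 to 89239656 on chromosome 5, Psmb8 34198195 to 34201454 on chromosome 17, and Col5a1 27886381 to 28039510 on chromosome 2. In the GENCODE vM21 annotation more than 10% of the exon bases were shared with a gene on the opposite strand for 9 of the 86 genes chosen for reporting: Sox4 (54.6%), Irs1 (30.9%), Ccnd1 (23.4%), Bnip3 (22.3%), Bhlhe41 (19.1%), Sox17 (16.9%), Bcat2 (15.95%), Psmb8 (14.7%) and Nmrk2 (14.6%). Whether the counting used strand is not given in the sources used here, so the values of these genes can include reads of their neighbours, and those of the Gbp family and H2-Aa reads of close paralogs.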

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

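The tests of exchanged treatment labels, of RNA from another cell type and of libraries of aged mice were chosen after the result was seen, and the regrouping tests were not. A library was listed as extreme when its gap to the nearest other library of its group took a share of the group's range above the 95% limit of Dixon's test for 6 values. Of 396 groups examined, 31 exceeded it, where chance marks about 1 in 20, or 19.8. Of these, 12 were in young vehicle 3, 6 in young dexamethasone 5 and 3 in young vehicle 5.

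Myod1, the myogenic transcription factor, was highest in young vehicle 3 at 9.59 (the nearest vehicle library was at 7.92; gap share 0.745) and in young dexamethasone 5 at 9.23 (nearest 7.70; 0.810). Rrad was also highest in both, at 11.66 (nearest 8.53; 0.715) and 10.49 (nearest 7.88; 0.705). In young vehicle 3, Ccr2 (0.641), Dio2 (0.634), Ifit3 (0.660), the interferon and antigen presentation list (0.746), the erythroid markers (0.639) and the oxidative stress list (0.633) were highest too, while Ddit4 (0.651), Fkbp5 (0.652), Rnf169 (0.749) and the negative regulators of mTORC1 (0.634) were lowest. In young dexamethasone 5, Ccnd1 (0.737), Lcn2 (0.722), Runx1 (0.725) and Stat2 (0.738) were highest. In young vehicle 5, Bcat2 (0.642), Cdkn1a (0.635) and Psmb9 (0.720) were lowest. Single cases in the young were Col5a1, highest in young dexamethasone 6 (0.705), and Cyp26b1, highest in young dexamethasone 4 (0.634). In the aged, Fosb (0.686) and Ifit3 (0.641) were highest in aged dexamethasone 1, Fbxo40 (0.728) lowest in aged dexamethasone 2, Tbc1d1 (0.761) lowest in aged dexamethasone 6, Gbp4 (0.658) lowest and Nr3c1, the glucocorticoid receptor gene (0.692), highest in aged vehicle 1. The amino acid list was highest in aged vehicle 4 (0.800) and the erythroid markers in aged vehicle 6 (0.795).

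Young vehicle 3 and young dexamethasone 5 shared high values of Myod1, Rrad, Fos (10.80 and 10.67) and Socs3 (10.50 and 10.86), of which Fos and Socs3 were named after their values were seen. An exchange of treatment labels is argued against, since the glucocorticoid target score of young vehicle 3 was −0.358 from the lowest other young dexamethasone library and that of young dexamethasone 5 lay 0.417 above the highest other vehicle library. Of 9 marker lists, 0 were above all other libraries of the group by more than their SD in both. This argues against RNA of the same listed cell type in both libraries. The test required a rise in both, so it could not decide on RNA of a listed cell type in a single library. The erythroid markers were listed as extreme in young vehicle 3 and not in young dexamethasone 5, so erythroid RNA in young vehicle 3 stays open. Myogenic and satellite cell genes and the markers of T, B and NK cells were not among the 9, so RNA of those cells stays open. Libraries of aged mice are argued against by collagen and matrix scores of 9.83 and 9.79, within the range of the other young libraries (9.38 to 9.85), the lower 0.715 above the highest aged library, although the ages were transformed apart and the Myod1 values of the pair lie in the range of the aged libraries (8.53 to 9.90), not of the other young ones (7.34 to 7.92). What sets the libraries apart stays open, and no biological explanation was tested, as the design gives none within a group.

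For the difference of effects between ages, camera called 7 lists, all toward a negative value of the aged effect minus the young effect: cytosolic ribosomal proteins (adjusted p = 2.97e-06), proteasome subunits (1.02e-05), interferon and antigen presentation (1.05e-05), oxidative stress (0.0145), cell cycle (0.0356), immediate early genes (0.0366) and erythroid markers (0.0445). That sign does not give the strength of a response. The ribosomal protein mean changed by −0.02 in the aged and 0.02 in the young, and the proteasome mean by −0.05 and 0.01. The interferon list mean changed by −0.33 in the aged and −0.16 in the young, and the immediate early mean by −0.05 and 0.19. The erythroid call rested on 3 genes. With an estimated correlation the adjusted p was 0.753 for each of the 7 lists, and with fry 0.788. The last 4 were also lost when some single libraries were left out, oxidative stress in 3 of 24 fits and the others in 8 to 10, and the proteasome, oxidative stress and immediate early calls without the libraries that stand apart (adjusted p = 0.0531, 0.0531 and 0.0913). At a minimum mean of 8 the cell cycle call was lost (camera adjusted p = 0.250), and with the replicate block the immediate early call (0.0664). Regrouping the libraries across ages within a treatment gave at least 7 lists in 80 of 100 draws (highest other 22), so chance is not excluded for them. At an unadjusted p under 0.05 the difference had 400 genes, and 62 of 100 regroupings gave as many, so chance is not excluded. The other regroupings had a median of 447. The highest, at 1868, was several times the real count, which points to a structure of the samples that was not tested further.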

How the results depend on the processing

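The fit of each age alone in place of the shared spread of the first design, the exact permutation test of list means, the minimum mean of 8 and the fits without the libraries that stand apart were chosen after the results were seen. In the aged, 533 genes were higher and 289 lower. The counts became 307 and 85 at an adjusted p under 0.01, 195 and 58 at an absolute difference of at least 0.5, and 710 and 534 with a shared spread. With library weights 438 were lower. Leaving out 1 library gave 411 to 614 higher and 167 to 433 lower, the lowest counts without aged dexamethasone 4, with 181 lower without aged dexamethasone 5. In the young, 478 were higher and 227 lower. The counts became 239 and 72 at the stricter p, 115 and 23 at the size limit, and 359 and 110 with a shared spread. Leaving out 1 library gave 341 to 476 higher and 152 to 219 lower. Without the libraries that stand apart they were 614 and 433 in the aged and 455 and 220 in the young. The exact permutation test gene by gene called 0 genes in each direction at either age, because its smallest p, 0.00216, was reached by 543 aged and 491 young genes where 560 and 557 would be needed to pass (smallest adjusted p 0.0515 and 0.0567). By limma at an unadjusted p under 0.05 there were 1197 higher and 1214 lower genes in the aged and 1121 and 948 in the young. Other filters, scaling and moderation kept every count within 1.5 times, and the median difference over all genes stayed between −0.0106 and 0.00101 at both ages under each scaling. Stricter thresholds lower the counts by construction, and the cause of the other shifts was not tested.

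For the difference of effects no setting that was run called a gene (400 at an unadjusted p under 0.05). Camera called 7 lists in the aged, 6 in the young and 7 for the difference. With an estimated correlation these were 0, 1 and 0, with fry 2, 2 and 0, and by the exact permutation test of list means 2 in the aged and 4 in the young. The lists called by fry were glucocorticoid receptor targets at both ages, negative regulators of mTORC1 in the aged (fry adjusted p = 0.0284) and the circadian clock in the young (fry adjusted p = 0.0330). The mixed form of fry asks whether a list's genes change in either direction. It called 19 lists in the aged, 14 in the young and 0 for the difference. Leaving out 1 library gave 4 to 10 lists in the aged (4 without aged dexamethasone 6), 5 to 9 in the young and 3 to 15 for the difference, and 12 without the libraries that stand apart. The difference count fell to 3 without aged dexamethasone 4 or young dexamethasone 5 and 4 without young vehicle 6, and was 11 to 15 without aged vehicle 1, 3 or 4, aged dexamethasone 3, young vehicle 3 or 5, or young dexamethasone 3, the last giving the highest. By list, macrophage markers in the aged lost their call at a minimum mean of 5 (adjusted p = 0.147) and with median centring (0.0516). With quantile normalisation the negative regulators of mTORC1 (0.0661) and the amino acid list (0.111) lost theirs in the aged, and immediate early genes in the young with a shared spread (0.109).

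The replicate numbers did not pair the samples: the deviations of same-numbered libraries correlated between −0.599 and 0.315 within an age, and the best match of a library was its own number for 2 of 6 aged and 1 of 6 young. With the replicate block 368 genes were higher and 160 lower in the aged and 326 and 118 in the young, the difference of effects stayed at 0 genes, and camera called 8 lists in the aged, 7 in the young and 6 for the difference.

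Of 125 calls of named genes, 82 were kept in all 21 or 22 refits (the stricter thresholds and the exact permutation test not among them), 39 of 64 in the aged and 43 of 61 in the young. Without a filter on low values the calls of Bcat2, Cyp26b1, Igf1r, Musk and Trim63 in the aged and of Acvr1b, Chac1, Ky, Lum, Podxl, Psmb8, Psmb9 and Slc7a5 in the young were lost. With quantile normalisation those of Bcat2, Bnip3, Dok7, Foxo1 and Trim63 in the aged and Acvr1b in the young were lost. The only changes of sign were in genes that did not pass. Per1 in aged mice (−0.01) was 0.0385 with library weights, 0.0414 without the libraries that stand apart, and −0.0739 (without aged dexamethasone 6) to 0.0467 (without aged dexamethasone 5) with 1 library left out. Tsc22d3 in aged mice (−0.02) was 0.0426 without the libraries that stand apart and −0.0806 to 0.0426 with 1 left out. Fbxo32 in aged mice (−0.07) was −0.17 to 0.040. Tsc22d3 in young mice (−0.03) was −0.0702 to 0.0111, and Myod1 in young mice (−0.12) was −0.41 to 0.21, the highest without young vehicle 3. Depth was unknown, so what it limits could not be weighed, except that rlog shrinks the differences of weakly expressed genes. Comparisons of aged with young levels, their alternatives, alternatives for counts, and an exact permutation test of the difference were not run.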

Other observations

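The tests of rlog shrinkage, of libraries that stand apart, of a lower share of non-muscle cells and the exact permutation test of list means were chosen after the result was seen. Single genes of further lists passed the threshold with dexamethasone, while camera called none of the lists they come from. At the neuromuscular junction, Musk, the receptor kinase that organises acetylcholine receptors, rose in the young (0.79, adjusted p = 0.0157) and in the aged (0.70, adjusted p = 0.0380, kept in 4 of 12 fits with 1 library left out, adjusted p up to 0.0901), and its activator Dok7 rose in the aged (0.31, adjusted p = 0.0538 without aged dexamethasone 3). Of 21 genes of the junction and of denervation, 2 were higher and 1, Runx1, lower in the aged, and 1 was higher in the young (2 higher and 2 lower, and 1 higher, adjusted over the list alone), without a call by camera at either age (adjusted p = 0.250 and 0.865). In the circadian clock list the activator gene Npas2 rose by 0.56 in the aged (adjusted p = 3.92e-05) and 0.53 in the young (adjusted p = 1.94e-04), and the repressor gene Bhlhe41 fell by 0.68 and 0.61. Of 21 clock genes, 1 was higher and 2 lower in the aged and 2 were higher and 1 lower in the young (camera adjusted p = 0.770 and 0.0699). Adjusted over the list alone these were 1 and 3 in the aged and 3 and 1 in the young. In the myostatin, activin and BMP list, of which 3 of 32 were higher in the aged (camera adjusted p = 0.387) and 3 of 31 higher and 1 lower in the young (0.201), the receptor gene Acvr1b rose by 0.55 in the aged and Tgfb3 by 0.41 in the aged and 0.29 in the young. Adjusted over the list alone, 6 were higher and 2 lower in the aged and 5 and 2 in the young.

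The angiopoietin receptor gene Tek fell by 0.56 in the aged and 0.53 in the young (adjusted p = 0.0105 and 4.27e-04), and Sox17, a transcription factor of arterial endothelium, rose by 0.81 and 0.47 (adjusted p = 0.00449 and 0.00692). Of 16 endothelial markers, 2 were higher and 3 lower at each age, without a call by camera (adjusted p = 0.533 and 0.0594). Adjusted over the list alone, 3 were higher and 5 lower in the aged and 2 higher and 7 lower in the young. Of the 74 cytosolic ribosomal protein genes, 32 proteasome subunits and 40 ribosome biogenesis genes tested, limma called 0 at either age. At an unadjusted p under 0.05 it gave 0 ribosomal protein genes at either age, 2 lower proteasome genes in the aged and 0 in the young, and in ribosome biogenesis 1 lower gene in the aged and 2 higher and 1 lower in the young. By the exact permutation test the mean of the senescence and p53 target list was 0.08 higher in the aged (adjusted p = 0.0433) and 0.10 in the young (adjusted p = 0.0211), in 6 of 6 libraries each. The median over its 20 genes was −0.04 in the aged, opposite in sign to the mean, and camera did not call it (adjusted p = 0.775 and 0.566). Of its genes 4 were higher and 2 lower in the aged (4 and 5 adjusted over the list alone) and 5 higher and 3 lower in the young (5 and 3). Cdkn1a (0.78 in the aged and 0.81 in the young) and Sesn1 (0.89 and 0.77) are also on the glucocorticoid receptor target list. The mean without them was not tested, so a rise apart from those targets was not shown. The autophagy and lysosome mean in the young was 0.05 higher (exact permutation test, adjusted p = 0.0211). Camera did not call that list (adjusted p = 0.162, and adjusted p = 0.830 with an estimated correlation), and 2 of its 34 members were higher and none lower (4 and 0 adjusted over the list alone).

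Chance was excluded for the number of genes changed at each age. In the aged, 1 of 100 splits, the real one, gave as many as 822 genes, and the highest other gave 0. In the young, 1 of 100 gave as many as 705, and the highest other gave 310. Chance was not excluded for the number of lists called by camera with its preset correlation, with at least 7 in 93 of 100 splits of the aged libraries (highest other 20) and at least 6 in 89 of 100 splits of the young (highest other 22).

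A first hypothesis is that dexamethasone had larger effects across genes in aged muscle. The SD of the effects over 12879 genes, with the noise between libraries subtracted, was 0.154 in the aged and 0.107 in the young, a ratio of 1.44 (1.31 to 1.58 with 1 library left out). Of the regroupings of libraries across ages, 2 of 100 gave a ratio as high (highest other 1.58), while 5 of 100 gave one as far from 1 in either direction, so chance was excluded only for a ratio as high. Shrinkage of low values by rlog in the young is argued against by a ratio of 1.45 among genes with a mean of at least 10, with 1.52 from 3 to under 6, 1.39 from 8, 1.57 from 12, and 1.44 after quantile normalisation, and the libraries that stand apart by a ratio of 1.57 without them. A difference of age in the response may be involved and stays open, as do unknown depth and separate transforms, and no single gene passed the test of the difference.

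A second hypothesis concerns the interferon and antigen presentation genes that were lower in the aged. Fewer macrophages in the treated muscle could account for part of them: with the macrophage marker score as a covariate the list's median difference was −0.218 (−0.296 to −0.194 with 1 library left out), against −0.31 without it. The difference shrank without going to 0, and fewer macrophages as the cause stays open. A lower share of all non-muscle cells was tested by the shift of macrophage and progenitor markers beyond that of endothelial, smooth muscle and Schwann cell markers, which was −0.218 (exact permutation test, p = 0.216) and left it open. A direct action of the drug on interferon signalling was not tested apart from these.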
